A study of Mus musculus with 6 samples.

How the data were processed

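Bulk RNA sequencing was available for the prefrontal cortex of 6 male C57BL/6J mice, 3 nonresponders and 3 responders to ketamine. Per the labels, each mouse received 10 mg/kg ketamine by intraperitoneal injection 24 hours before the tissue was taken. Mice were siblings housed 3 per cage, polyA RNA was sequenced after preparation with a SMARTER RNA library kit, and all 6 libraries carry batch number 1. Each library came from a different mouse per the labels' protocols, so the spread between replicates covers differences between mice as well as technical variation. The mouse genome build mm10 is named per the submitters' processing notes. The aligner, the counting tool, its strand setting and the authors' test are not given in the sources used here.

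The deposited table held 1375 genes, each with whole read counts per library, per the file headers. The authors' FPKM values (fragments per kilobase of gene and per unit of library scale) equalled the deposited count divided by the deposited gene length and by 1 scale number per library, which was the same for every gene. That scale lay between 14981505 and 19298950 reads. The authors' deposited log2 fold change was that of nonresponders over responders, and was below 0 in every gene. Its median absolute difference from the log2 ratio of the group mean FPKM values was 0.00099. The authors' deposited p-value was below 0.05 in all 1375 genes. The table is therefore a selection by p-value and by direction, and genes that were lower in responders were not analysed here. The authors' deposited adjusted p-values have the form of a Benjamini-Hochberg adjustment over 14156 genes, a number inferred from the ranks of 113 genes, of which 51 gave a whole rank within 0.01. By these ranks, 64 genes at or before the last listed gene with an adjusted p-value below 0.05 stand outside the table and were not analysed here. In 108 genes the deposited adjusted p-value was exactly 1. The table also held 6 columns of values per sample that match no label; they were not used.

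The depth of each library is unknown, because the counts cover the listed genes alone. These summed to between 1989534 and 3486903 reads per library. Of the gene identifiers, 1373 were found in GENCODE release M21, of which 1323 had the same start, end and strand; positions are printed as the authors' table gives them. Biotypes, gene length and strand also come from that table, and GC content from the annotation's transcripts.

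The design fixed before the data were examined foresaw a table of selected genes. For that case the authors' p-values were to be copied and counted at an adjusted threshold of 0.05, per-gene values described, and no test of gene lists made. FPKM values per mouse were averaged within a group and are given as mean ± SD, and folds and log2 differences are ratios of these means, with responders over nonresponders. No pseudocount was added, and 1358 genes with a mean above 0 in both groups had a ratio. Members of 28 gene lists fixed beforehand (15 of pathways and families, 13 of cell type markers) were counted. Counts "adjusted over the list alone" apply the Benjamini-Hochberg adjustment to the deposited p-values over all members of the list, with members outside the table given a p of 1. As every listed gene already had a small p-value, such counts are descriptions. Any list member outside the table has no value here.

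Genes were named by a rule fixed before the data were examined. It took the 12 largest rises among genes past the threshold whose groups did not overlap and whose mean FPKM was at or above 12.3, the median of the table. It added up to 4 members per list past the threshold and 10 genes often discussed for ketamine, of which 1 was in the table. The rule gave 16 genes. The other 4 genes past the threshold, and the examples that did not pass (the 4 smallest deposited p-values of a list), were chosen after their values were seen.

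Chosen after seeing the data were the following steps. The counts of the listed genes were refitted with edgeR 4.0.16 (quasi-likelihood test, robust, two-sided) and with DESeq2 1.42.0 (Wald test), with the authors' scale as library size. Benjamini-Hochberg adjustment counted 14156 tests, with genes outside the table treated as not passing, which is conservative in the number of tests only. The listed genes had been selected by p-value in the same mice, so these adjusted values describe them and are no discovery test. The dispersion trend in the refits comes from selected genes. No p-value is given for a list, since its genes were selected and measured in the same mice and are not independent. A list's median was placed among the medians of 10000 random lists of listed genes matched on mean FPKM, gene length or GC content. Mitochondrial ribosomal proteins and proteasome subunits were added as families. Responder replicate 3 was singled out for values without it, while leaving out each replicate in turn had been planned. The edgeR step was tested on simulated counts for 1303 listed genes with a dispersion of 0.01. It recovered 92% of 100 genes changed 1.5-fold and 98% of 100 changed 2-fold, and called 0.453% of unchanged genes, with adjustment over the simulated genes. No simulated library stood apart from the others as responder replicate 3 does. These shares therefore do not give the power of the refit of the real counts, which called 0 genes with all 6 libraries. Alternatives were other thresholds, a minimum fold, each replicate left out, a replicate block, a count filter and DESeq2. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3, were used.

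Reads of near-identical copies cannot be told apart from these counts. This concerns Hspa1b with its neighbour Hspa1a, ribosomal protein genes with their many processed pseudogenes, and mitochondrial genes with their nuclear copies, whose values are uncertain for that reason. Without a stated strand setting, overlapping and antisense genes are uncertain too.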

Results

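The data were gene expression values in the prefrontal cortex of 6 male mice of the inbred strain C57BL/6J, all given ketamine, an NMDA receptor antagonist with rapid antidepressant action, 24 hours before. The mice had been sorted by behaviour in the novelty suppressed feeding and forced swimming tests into 3 responders and 3 nonresponders. There were no untreated mice among the samples, so the values compare ketamine-treated mice with each other. Over the 1375 listed genes, the nonresponder libraries held 2260015, 1989534 and 2344489 reads and the responder libraries 2464228, 2430688 and 3486903 reads. Each of the listed genes had been selected by the authors as higher in responders, so the comparison describes which genes were higher and by how much.

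The comparison of responders with nonresponders asks which genes differed in prefrontal cortex between mice that did and did not show the behavioural effect of ketamine. Among the listed genes, those with the smallest adjusted p-values in the authors' deposited table were Hspa5, Xbp1, Manf and Pdia6, all tied to protein folding in the endoplasmic reticulum (ER). Hspa5, the ER chaperone BiP, stood at 55.5 ± 3.41 FPKM (SD, n = 3) in nonresponders and 94.6 ± 2.09 FPKM (SD, n = 3) in responders, a 1.71-fold difference. Xbp1, a transcription factor of the unfolded protein response, stood at 19.8 ± 0.592 and 32.5 ± 3.42 FPKM (SD, n = 3 per group), a 1.64-fold difference. Manf, a secreted protein induced by ER stress, stood at 7.46 ± 0.612 and 14.1 ± 2.89 FPKM (SD, n = 3 per group), 1.89-fold higher in responders. In the authors' deposited table, the adjusted p-value was 1.78e-07 for Hspa5, 0.000647 for Xbp1 and 0.00121 for Manf. Across all listed genes, the median fold was 1.48, the middle 50% lay between 1.35 and 1.72, and 180 of 1358 genes were at least 2-fold higher.

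At an adjusted p-value of 0.05 in the authors' deposited table, 19 of the 1375 listed genes passed, all of them higher in responders. By the ranks that the adjusted p-values of the authors' deposited table imply, 64 further genes at or before the last of the 19 were not analysed here. If the table holds every gene with a p-value below 0.05 that was higher in responders, those 64 were lower in responders. Of the 19 genes, 10 belong to the list of heat shock and ER stress genes fixed beforehand, of whose 22 members 15 were in the table. The 10 were Hspa5, Xbp1, Manf, Pdia6, Dnajb11, Pdia4, Hspa1b, Calr, Hsp90b1 and Sdf2l1. All 15 members in the table passed when adjusted over the list alone, by the p-values of the authors' deposited table. Their median log2 difference was 0.65, ranging from 0.33 to 0.92, and in all 15 every responder lay above every nonresponder. Among the other 1360 listed genes, 9 passed in the authors' deposited table.

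The members of this list cover several steps of protein folding. Pdia6 and Pdia4, protein disulfide isomerases, were 1.69-fold and 1.57-fold higher in responders. Dnajb11, a cochaperone of BiP, stood at 13.0 ± 0.319 FPKM in nonresponders and 18.7 ± 0.564 FPKM in responders (SD, n = 3 per group). Hsp90b1, the ER form of Hsp90, was 1.45-fold higher, and Sdf2l1, an ER-resident component of chaperone complexes, was 1.77-fold higher. Calr, the lectin chaperone calreticulin, was the most abundant of the 10, at 105 ± 4.28 and 145 ± 11.5 FPKM (SD, n = 3 per group). Hspa1b, the inducible cytosolic Hsp70, stood at 3.19 ± 0.154 and 5.39 ± 0.358 FPKM (SD, n = 3 per group), 1.69-fold higher, although its reads may be shared with Hspa1a. Hspa1b and Calr fell outside the naming rule and were chosen after their values were seen. In the authors' deposited table, the adjusted p-values of Pdia6, Dnajb11, Pdia4, Hspa1b, Calr, Hsp90b1 and Sdf2l1 lay between 0.00425 and 0.0369. Members that did not pass included Creld2 at 1.58-fold, with an adjusted p-value of 0.0617 in the authors' deposited table, and the abundant cytosolic chaperones Hspa8 at 1.40-fold (adjusted p-value 0.127) and Hsp90aa1 at 1.45-fold (adjusted p-value 0.135). Without responder replicate 3, the log2 differences of Hspa8 and Hsp90aa1 were 0.31 and 0.30, in place of 0.48 and 0.53.

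**Figure D1:**
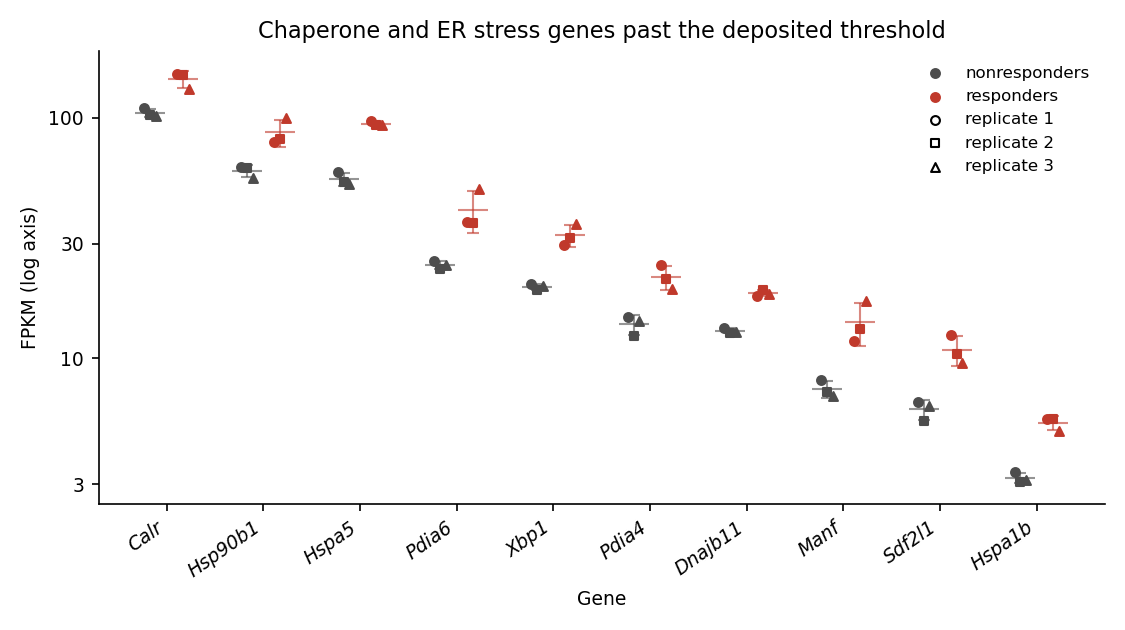
FPKM (log axis) of the 10 heat shock and ER stress genes that passed the deposited threshold, in each of the 3 nonresponders (grey) and 3 responders (red); horizontal bars are group means and vertical bars are SD. In each gene all responders lie above all nonresponders, from Hspa1b near 3.19 and 5.39 FPKM to Calr near 105 and 145 FPKM.

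Pdia3 and Chordc1, outside the list, also act in protein folding, as a disulfide isomerase and an Hsp90 cochaperone. Pdia3 rose from 57.6 ± 3.73 to 85.2 ± 7.80 FPKM (SD, n = 3 per group) between nonresponders and responders, and Chordc1 from 10.8 ± 0.246 to 15.0 ± 0.745 FPKM (SD, n = 3 per group). The other 7 genes past the threshold were Ptgds, Scg2, Dio2, Rlbp1, Kcnj2, Gjb6 and Igfbp2. Scg2, the dense core vesicle protein secretogranin 2, was 1.46-fold higher, at 79.8 ± 6.80 and 117 ± 8.37 FPKM (SD, n = 3 per group). Dio2, the deiodinase that activates thyroid hormone, was 1.58-fold higher. Gjb6, the astrocyte gap junction protein connexin 30, was 1.65-fold higher, and Igfbp2, which binds insulin-like growth factors, 1.62-fold higher. Rlbp1, a retinaldehyde-binding protein, and Kcnj2, an inward rectifier potassium channel, were 1.68-fold and 1.83-fold higher; both fell outside the naming rule and were chosen after their values were seen. In the authors' deposited table, the adjusted p-values of Pdia3, Chordc1, Scg2, Dio2, Gjb6, Igfbp2, Rlbp1 and Kcnj2 lay between 0.0130 and 0.0460.

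Ptgds, the brain prostaglandin D2 synthase, was the 1 gene of the 19 that was over 2-fold higher, at 40.2 ± 1.62 FPKM in nonresponders and 87.2 ± 35.1 FPKM in responders (SD, n = 3 per group). Its adjusted p-value in the authors' deposited table was 0.0143. Responder replicate 2 stood at 47.7 FPKM, near the 38.7 to 41.9 FPKM of the nonresponders, while responder replicates 1 and 3 stood at 99.3 and 115 FPKM. The listed leptomeningeal markers had medians in the same order, at 0.58 on the log2 scale over the nonresponder mean in responder replicate 2 and 1.21 and 1.29 in replicates 1 and 3. In nonresponder replicates 1, 2 and 3 the marker medians were -0.81, 0.14 and 0.40. Ptgds did not follow them in size there, moving only from 38.7 to 41.9 FPKM. In edgeR's quasi-likelihood refit, the log2 difference of Ptgds was 1.12 with all 6 libraries, 0.87 without responder replicate 3 and 1.41 without responder replicate 2. The unadjusted p of Ptgds by that model, fitted across the listed genes, was 0.00856, 0.0904 and 0.000104 in these settings.

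By the mm10 positions of the table, Hspa5 is on chromosome 2 from 34771970 to 34777547 on the plus strand, and Xbp1 on chromosome 11 from 5520659 to 5525893 on the plus strand. Manf is on chromosome 9 from 106838312 to 106891979 on the minus strand. Ptgds is on chromosome 2 from 25466709 to 25470046 on the minus strand. All 4 are protein coding genes with the identifiers ENSMUSG00000026864, ENSMUSG00000020484, ENSMUSG00000032575 and ENSMUSG00000015090.

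The 19 calls were not reproduced at an adjusted p of 0.05 in refits of the listed counts with all 6 libraries. These gave 0 genes by edgeR's quasi-likelihood test and 1, Hspa5, by DESeq2. The refits also treated genes outside the table as not passing and took the dispersion trend from selected genes. The unadjusted p of the 19 genes lay between 0.000364 and 0.0135 in the edgeR refit. In the authors' deposited table it lay between 1.25e-11 and 0.00027. The treatment of genes outside the table acts on the adjustment only, so it does not account for these larger values. How much each choice lowered the count was not tested. At an unadjusted p of 0.05 those refits gave 365 and 584 of the 1375 listed genes, the 19 included; by edgeR there were 101, 87 and 117 without nonresponder replicates 1, 2 and 3, and 787, 560 and 828 without the same replicates of the responders, and the setting without responder replicate 3 gave 75 genes at an adjusted p of 0.05, among them all of the 19 but Ptgds.

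Responder replicate 3 stood apart from the other 5 libraries over the listed genes. These had been selected for being higher in responders with that library included, so how it stands over all genes is unknown. It was the highest of the 6 in 1204 of the 1375 listed genes, against 82 and 89 genes for responder replicates 1 and 2. Its Pearson correlations with the other libraries over log2(FPKM + 1) were 0.967 to 0.972, and those of the other pairs were 0.993 to 0.996 after rounding. Its median FPKM over listed genes was 18.8, compared with 11.4 and 11.9 in the other responders and 9.48 to 10.0 in the nonresponders. Without it, the median log2 difference of all listed genes was 0.26 in place of 0.57. In 1374 of the 1375 listed genes the mean of responder replicates 1 and 2 still lay above the nonresponder mean. Every responder lay above every nonresponder in 1010 genes; chance gives such a separation, in either direction, in 10% of unselected genes.

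None of the listed genes of the ribosome, the respiratory chain and the mitochondrial genome passed the adjusted threshold of the authors' deposited table. The median of each list was highest in responder replicate 3, as were those of chaperone genes and of all listed genes. The log2 medians there over the nonresponder mean were 1.32 for the ribosome, 1.29 for the respiratory chain and 1.02 for all listed genes. Mitochondrial genome genes, at 0.98, and chaperone genes, at 0.64, lay below the median of all listed genes. Of 80 cytosolic ribosomal protein genes, 27 were in the table, with a median log2 difference of 0.70 that was 0.28 without responder replicate 3. Rps9 stood at 33.2 to 34.9 FPKM in nonresponders, 41.6 and 41.4 FPKM in responder replicates 1 and 2, and 103 FPKM in replicate 3. Of 83 nuclear genes of the respiratory chain, 24 were in the table, with a median log2 difference of 0.64, or 0.18 without that library. Ndufa12, a subunit of complex I, stood at 26.2 to 29.4 FPKM in nonresponders, 34.1 and 35.1 FPKM in responder replicates 1 and 2, and 82.4 FPKM in replicate 3. In the authors' deposited table, the adjusted p-values were 0.137 for Rps9 and 0.128 for Ndufa12. Replicate 3 of the responders was the highest library for all 27 ribosomal and all 24 respiratory chain genes, against 1204 of all 1375 listed genes. No member of either list passed when adjusted over the list alone, by the p-values of the authors' deposited table. In the edgeR refit without responder replicate 3, 22 of the 27 ribosomal genes had an unadjusted p under 0.05 and 6 an adjusted p under 0.05 (Rpl36a, Rpl21, Rpl35a, Rps26, Rpl23a and Rpl26). Of the 24 respiratory chain genes, 10 and 2 did (Uqcrb and Ndufs6 by adjusted p).

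Of 13 protein genes of the mitochondrial genome, 8 were in the table, with a median log2 difference of 0.60, or 0.26 without responder replicate 3. All 8 passed when adjusted over the list alone and 0 when adjusted over all genes, by the authors' deposited table. Every responder lay above every nonresponder in 3 of the 8, against 1010 of all 1375 listed genes. In the edgeR refit 1 of the 8 had an unadjusted p under 0.05. Without responder replicate 3 there were 5, and 0 by adjusted p. The most abundant, mt-Co1, stood at 8932 to 10150 FPKM in nonresponders, 10273 and 11984 FPKM in responder replicates 1 and 2, and 23582 FPKM in replicate 3. Reads of all listed genes on the mitochondrial chromosome made up 27.0% to 32.9% of all listed reads, the highest share in responder replicate 3. That share includes 1 ribosomal RNA gene and 3 transfer RNA genes besides the protein genes.

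**Figure D2:**
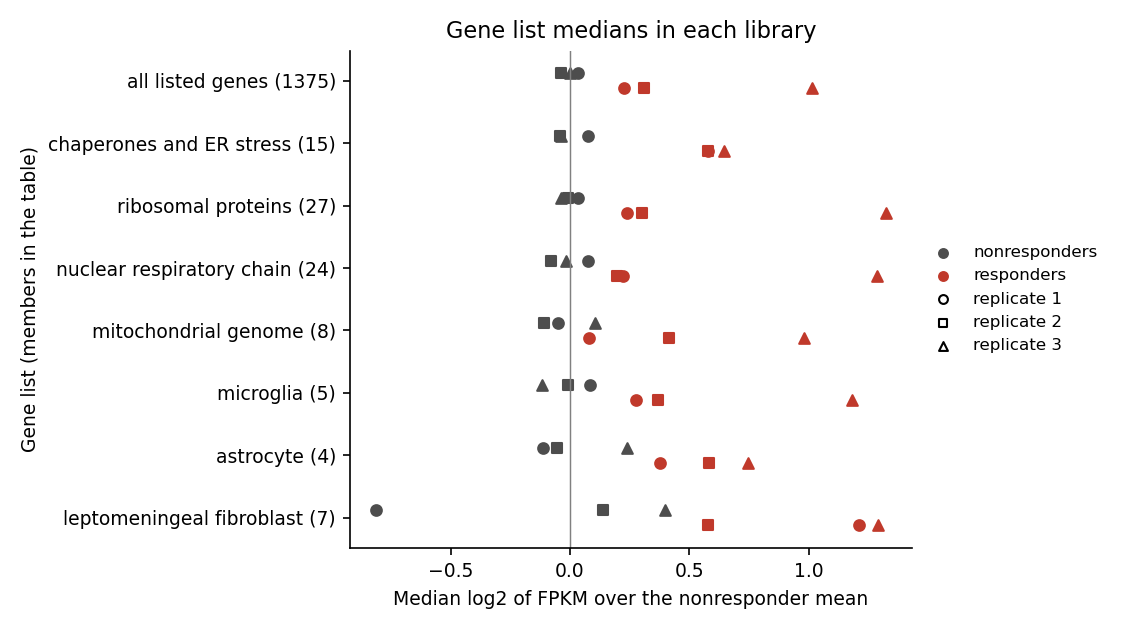
Median over the listed members of each gene list of the log2 ratio of FPKM to the nonresponder mean, for each of the 3 nonresponders (grey) and 3 responders (red), with the number of members in brackets. Chaperone and ER stress genes lie at 0.58, 0.58 and 0.64 in the 3 responders, while ribosomal protein genes lie at 0.24, 0.30 and 1.32.

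Genes tied to the action of ketamine in earlier work were mostly outside the table. Of the 10 named beforehand, Bdnf, brain-derived neurotrophic factor, was in it, at 6.91 ± 0.294 FPKM in nonresponders and 9.31 ± 1.89 FPKM in responders (SD, n = 3 per group), 1.35-fold higher. Its adjusted p-value in the authors' deposited table was 0.208, which did not pass. Of 26 genes of BDNF and mTOR signalling, Bdnf, Eif4e at 1.29-fold and Rheb at 1.48-fold were in the table, and 0 passed. Without responder replicate 3 the log2 difference of Bdnf was 0.25 in place of 0.43, that of Eif4e 0.24 in place of 0.36, that of Rheb 0.14 in place of 0.57, and the median of the 3 was 0.24 in place of 0.43. Of 30 immediate early genes, Homer1 and Bdnf were in the table. Homer1, a postsynaptic scaffold protein, stood at 21.1 ± 1.94 and 30.2 ± 5.27 FPKM (SD, n = 3 per group), with an adjusted p-value of 0.0987 that is taken from the authors' deposited table. It was also the 1 member in the table of 37 synapse genes. None of 25 glutamate receptor genes, 32 monoamine system genes and 29 voltage-gated channel genes was in the table.

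Further lists had few listed members, and none of these passed. Of 23 glucocorticoid response genes, Fkbp5 at 1.34-fold, Mt1 at 1.64-fold, Cdkn1a at 1.37-fold and Mt2 were in the table, with a median log2 difference of 0.59. The groups overlapped in Mt1 and Cdkn1a, and Mt2 had 4 to 23 reads per library. Among GABA system genes, the receptor subunit Gabrg1 was 1.44-fold higher in responders. Of 8 opioid system genes, Penk, which encodes proenkephalin, was in the table with a log2 difference of 0.58. Of 18 clock genes, Rorb was in the table at 1.22-fold, and of 30 interferon and inflammation genes, B2m at 1.49-fold. Without responder replicate 3, the log2 difference was 0.24 in place of 0.72 for Mt1, 0.21 in place of 0.52 for Gabrg1, 0.33 in place of 0.58 for Penk and 0.13 in place of 0.57 for B2m.

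Among cell type markers, those of leptomeningeal fibroblasts, cells of the membranes covering the cortex, showed the largest median difference of the fixed lists with at least 3 members in the table. Of 12 such markers, 7 were in the table, with a median log2 difference of 1.01, or 0.94 without responder replicate 3. The latter was at the 46.0th percentile of random lists of listed genes matched on FPKM, so the list did not stand out for its abundance. By the authors' deposited table, Igfbp2 passed over all genes, and 6 members passed when adjusted over the list alone. The collagen-associated proteoglycan Lum was low, at 0.0875 to 0.275 FPKM in nonresponders and 0.534 to 1.58 FPKM in responders, on 4 to 58 reads. In 6 of the 7 every responder lay above every nonresponder, and in Ogn the groups overlapped. Of 12 astrocyte markers, Gjb6, Gfap at 1.66-fold, Aqp4 at 1.41-fold and Aldoc at 1.35-fold were in the table, with a median log2 difference of 0.61. Without responder replicate 3 the log2 difference of Aldoc was 0.27 in place of 0.43, and without nonresponder replicate 1, which stood at 7.08 FPKM, that of Gfap was 0.46 in place of 0.73. Gjb6 alone of these passed in the authors' deposited table, and all 4 passed when adjusted over the list alone.

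Of 15 microglia markers, Tyrobp, C1qa, C1qb, C1qc and Tmem119 were in the table, with a median log2 difference of 0.66, or 0.31 without responder replicate 3. None passed in the authors' deposited table, where 3 passed when adjusted over the list alone. Of 17 interneuron markers, Vip at 1.56-fold, Calb2 at 1.32-fold, Pvalb at 1.64-fold and Crh at 1.58-fold were in the table, and 0 passed. Their median log2 difference was 0.65, or 0.25 without responder replicate 3, and those of Vip and Crh were 0.64 and 0.66, or 0.25 each; that of Pvalb was 0.71, or 0.07 without that library, and nonresponder replicate 1 at 17.0 FPKM lay above responder replicates 1 and 2 at 14.9 and 12.1 FPKM. Of 18 excitatory neuron markers, Slc17a6 at 1.68-fold, Lamp5 at 1.25-fold (log2 difference 0.32, or 0.17 without responder replicate 3) and Rorb were in the table; 0 passed over all genes and 1 when adjusted over the list alone, by the authors' deposited table.

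A single member was in the table of 9 markers of oligodendrocyte precursors (Gpr17, 1.33-fold), of 13 endothelial markers (Slco1c1, 1.40-fold) and of 12 markers of choroid plexus and ependyma (Kl, 1.53-fold). Markers of tissue near the prefrontal cortex were few: of 15 for striatal projection neurons, Tac1 at 1.79-fold and Penk were in the table, and of 9 for the olfactory bulb, Trh at 1.75-fold and Synpr at 1.31-fold. None of these passed. The log2 differences of Slco1c1, Tac1, Penk and Synpr were 0.25, 0.35, 0.33 and 0.21 without responder replicate 3, in place of 0.49, 0.84, 0.58 and 0.39. No member of the lists for oligodendrocytes (16 genes), mural cells (10 genes) and blood (7 genes) was in the table. A gene outside the table may have been lower in responders or have differed less, and the counts do not tell these apart.

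Responder replicate 3 also differed from the other responders by gene length. The Spearman correlation, across 1251 listed genes with a mean of at least 1 FPKM, between gene length and its log2 ratio to the other responders was -0.48; genes are not independent replicates, and no p is given. The same correlation for the 5 other contrasts between libraries lay between -0.17 and 0.11. The median ratio was 2.24-fold among the shortest listed genes, of 56 to 1394 bases, and 1.32-fold among the longest, of 4602 to 20117 bases. Responder replicates 1 and 2 differed from each other by GC content. The Spearman correlation of their log2 ratio with GC content was 0.40, against 0.04 for replicate 3 over the other responders.

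**Figure D3:**
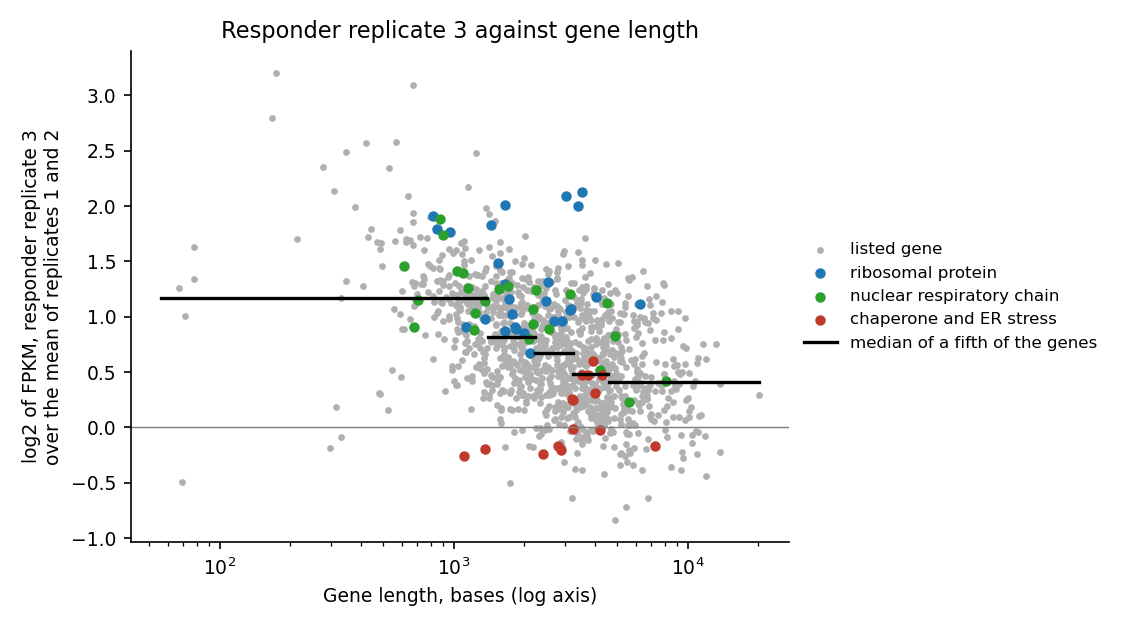
Log2 ratio of FPKM in responder replicate 3 to the mean of responder replicates 1 and 2 against gene length in bases (log axis), each point a listed gene with a mean of at least 1 FPKM; black lines are medians of 5 equal groups of all listed genes by length. The medians go from 1.17 in the shortest group to 0.41 in the longest, and the chaperone and ER stress genes (red), with a median of -0.01, lie below those of ribosomal proteins (blue) and the respiratory chain (green), with medians of 1.14 and 1.13.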

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

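The refits of the listed genes were chosen after seeing the data; the settings applied to them were planned. The 19 genes past the deposited adjusted p of 0.05 became 50 at 0.10, 368 at an unadjusted p of 0.01, 1375 at an unadjusted p of 0.05, and 1 with a minimum of 2-fold (Ptgds); with 1.5-fold they were 13. The edgeR refit with all 6 libraries gave 365 genes at an unadjusted p of 0.05 and 0 at an adjusted p of 0.05. With each replicate left out these counts ranged from 87 to 828 and from 0 to 75. All 3 settings without a nonresponder lowered the first count, to 101, 87 and 117, and all 3 without a responder raised it, to 787, 560 and 828; the cause was not tested. DESeq2 gave 584 and 1. A filter of at least 10 reads in every library of 1 group gave 314 and 0.

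The labels do not say that the replicate numbers pair mice. Same-numbered libraries had correlations of deviations from the group means of -0.06, -0.06 and -0.03, and the other pairs -0.03 to 0.10. With 3 libraries per group, and responder replicate 3 far from the other responders, these values can neither show nor exclude pairing. A fit with the number as a replicate block gave 222 and 0 genes. No library correlated best with its own number.

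The median log2 difference of chaperone and ER stress genes ranged from 0.57 to 0.70 with each replicate left out. Of its 15 listed members, 14 had an unadjusted p under 0.05 in the edgeR refit, and 9 to 15 with each replicate left out. Medians of 10 other lists were recomputed the same way and stayed above 0, which the selection of the table made nearly certain; the added families and lists with fewer than 3 members in the table were not. Of 20 genes named by the rule or past the threshold, 20 kept their side of an unadjusted p of 0.05 in the block and filter refits and 19 with DESeq2; with 1 replicate left out, up to 4 (without nonresponder replicate 2) no longer passed. List tests by camera and fry, other scalings, pseudocounts and a fit without a filter on all genes were not run, since the table holds selected genes of 1 direction. The unknown library depth leaves the reads per gene as the limit, such as 4 to 58 for Lum.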

Other observations

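All gene choices, the families added, the test of a single scaling and the tests without responder replicate 3 in this part were made after the results were seen; the tests against length, GC content and leptomeningeal genes were set before theirs were. Stip1, an Hsp70 and Hsp90 cochaperone outside the fixed lists, did not pass, at 1.34-fold with an adjusted p-value of 0.0704 in the authors' deposited table. In the edgeR refit without responder replicate 3, adjusted over 14156 tests, 57 listed genes beyond the deposited calls had an adjusted p under 0.05. Homer1 was 1.57-fold higher in responder replicates 1 and 2 than in nonresponders (adjusted p = 2.62e-07 by edgeR), and stood at 24.3 FPKM in responder replicate 3 against 21.1 in nonresponders. Lrfn2, a synaptic adhesion protein, was 1.64-fold higher in those 2 responders (adjusted p = 5.95e-05 by edgeR), at 6.78 FPKM in nonresponders and 7.15 FPKM in responder replicate 3. In the same 2 responders, Inhba, the activin A subunit, was higher by 0.58 on the log2 scale (adjusted p = 0.00400 by edgeR), and Klf6, a zinc finger transcription factor, 1.48-fold higher (adjusted p = 0.000156 by edgeR). The log2 ratio of responder replicate 3 to those 2 was -0.39 for Inhba and -0.42 for Klf6, and Klf6 stood at 14.7 FPKM there and at 11.4 to 14.4 FPKM in nonresponders. The adjusted p-values of Homer1, Lrfn2, Inhba and Klf6 in the authors' deposited table, 0.0987, 0.196, 0.205 and 0.197, did not pass. The genes were selected by p-value for being higher in responders in the same mice, and this fit kept 2 responders. These values therefore describe the listed genes only and are no discovery test.

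Mitochondrial ribosomal proteins and proteasome subunits, families added after seeing the table, were also highest in responder replicate 3. Of 78 mitochondrial ribosomal protein genes 38 were in the table, with a median log2 difference of 0.65, or 0.25 without responder replicate 3. Of 40 proteasome genes 17 were in the table, with a median of 0.66, or 0.19 without that library. That library was the highest in all 38 and all 17, against 1204 of all 1375 listed genes, and 0 of either family passed in the authors' deposited table. Fabp7, a fatty acid binding protein of radial glia and astrocytes, stood at 61.9 FPKM in responder replicate 3 and 5.68 to 8.46 FPKM in nonresponders, with responder replicates 1 and 2 above every nonresponder, the lower of them at 10.1 FPKM. Its adjusted p-value was 0.210 in the authors' deposited table, and its adjusted p by edgeR without responder replicate 3 was 0.0198, at 1.65-fold.

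Ribosomal and respiratory chain genes stood highest in responder replicate 3. A single scaling error of that library would raise all genes alike, but the median log2 excess of these 51 genes was 1.15 above that of chaperone genes. The 95% bootstrap interval, drawn over genes and not over mice, was 0.69 to 1.36. Gene length may account for part of it: lists matched on length had medians between 0.63 and 1.01, against 1.14 observed, which left 0.33 unaccounted for. The length matched was the deposited gene length, 6270 bases for Rps15a, which may differ from that of the transcripts sequenced. The 0.33 therefore cannot show a part beyond length. Lists matched on GC content left 0.46. RNA integrity or handling of that sample was not tested, and as the pattern is in 1 mouse, no biological explanation was tested.

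The 15 listed chaperone and ER stress genes were each higher in all 3 responders than in any nonresponder. Responder replicate 3 alone would leave no difference without it. Without it the median log2 difference was 0.58, with a 95% bootstrap interval over genes, not mice, of 0.38 to 0.72. It stood above all 10000 random lists of listed genes matched on FPKM. Ribosomal protein genes, with a median of 0.28, also stood above all of theirs, and astrocyte markers, with 0.48, at percentile 99.8. Length-matched lists had medians 0.33 lower. These ranks cannot decide on that library or on gene length, since the table was selected with replicate 3 included. Listed genes with no excess there, as these with a median of -0.01, needed a difference in the other responders. A median above 0 was also nearly fixed, as 1374 of the 1375 listed genes stayed higher. The values show only that the 15 genes were also higher in replicates 1 and 2. Within groups the score of these genes had a correlation of 0.057 with that of leptomeningeal genes over the 6 libraries (permutation p = 0.944, 36 permutations), too few libraries to decide whether varying dissection contributes. A difference tied to the ketamine response is a hypothesis that stays open beside effects of cage, dissection order or the swimming test, which the labels do not separate from the groups.

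The 7 listed leptomeningeal fibroblast genes had a median log2 difference of 1.01, and 1, Igfbp2, passed in the authors' deposited table. Without responder replicate 3 their median log2 difference was 0.94 (95% bootstrap interval over genes, not mice, 0.68 to 1.38). That was the 46.0th percentile of random lists of listed genes matched on FPKM, so the list did not stand out among them. The selection of the table keeps open a part of that library in these genes. Varying amounts of leptomeningeal tissue could raise them together: their mean pairwise correlation within groups was 0.47, against a median of 0.21 in random lists (percentile 82.9), which does not decide. Igfbp2, the most abundant listed member and also expressed by astrocytes, stood at 6.33 FPKM in nonresponders and 10.3 FPKM in responders. The membranes' amount in each dissection and a difference between the groups cannot be told apart with 3 mice each.

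Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many as its 365 listed genes at an unadjusted p of 0.05, and the highest of the others gave 175. The share cannot fall under 0.1 with 10 splits, and the genes had been selected for this split.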
